A study of Mus musculus with 2 samples.

How the data were processed

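RNA was sequenced from 2 samples of primary mouse fetal liver cells at day 15.5, 1 Atf4 knockout and 1 wild type, both with the cell type LSK, sorted by flow cytometry and not treated, per the labels. The sample titles carry the letters SC, which the labels do not expand, and the design text speaks of stromal as well as LSK cells. The cell type label was followed, and what SC stands for is not given in the sources used here. Total RNA was extracted with TRIzol and made into Illumina libraries, per the labels' protocols. The submitters' processing notes name TopHat, HTSeq 0.5.3p9, DESeq 1.16.0 and the mouse build mm9, without their settings or order. The annotation and the use of strand in counting are not given in the sources used here. Reads of overlapping genes, and of near-identical copies such as the adult globin, histone and ribosomal protein genes, may therefore be assigned to either or left uncounted. Their values are uncertain.

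The authors deposited 1 table of raw counts per gene symbol with 1 column per library, whole numbers that were not normalized. It lists 12898 genes, and each has at least 6 reads in at least 1 library, as checked on the table. Genes without a row are not analysed here, and no level is read from a missing row. The columns sum to 15774824 reads for the knockout and 14049374 for the wild type. The 10 most abundant genes took 8.12% and 13.1% of these reads.

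Samples were grouped by the genotype in the labels. With 1 library per group no test between genotypes can be made, so edgeR's quasi-likelihood test and DESeq2's test were not run and no p-value is given. The 2 libraries were described by a rule of size that was fixed, with the gene lists and alternatives, before the data were examined. Counts were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3), which were 1.08 for the knockout and 0.924 for the wild type. A gene passed when its scaled ratio was at least 2 or at most 0.5 and its 95% interval excluded 1, over the 11555 genes with at least 20 reads in both libraries together. The interval is the exact Clopper-Pearson interval on the knockout share of the gene's reads. It covers counting error only, not the variation between animals, sorts or library preparations. Log2 ratios used a prior count of 2. A gene with 0 reads in a library was given as a bound at a floor of 3 reads in that library.

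For each of 34 gene lists the median log2 ratio over tested members was given with an exact order-statistic 95% interval where there were at least 6 members, and with its rank among 10000 random lists of the same size matched on mean expression in 20 bins (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). The lists given by symbol held 495 symbols, of which 395 had a row, 4 of them found through an older or newer symbol, and 33 of the 34 lists had a tested member. Genes were named by a fixed rule. It took Atf4 and Angptl3, the 12 genes each way with the largest bound of the interval nearest to 1, and the 8 most abundant genes each way whose bound was at least 2-fold. It also took, in each list, the members with the largest such bound each way, the 3 most abundant members and any member at least 2-fold apart. Predicted genes, clone names and small RNA names were left out of the naming by rank. Other members are named where their levels bear on cell type, on an ATF4 or p53 list or on a described group, and were chosen after their values were seen.

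Transcript length and GC content came from the longest transcript of each symbol in GENCODE M21, which is on another build than the counts, so no coordinates are given. They were found for 98.2% of tested genes. Lowess trends (statsmodels 0.14.6, fraction 0.3) on length and then on GC content were subtracted from the log2 ratios as an alternative chosen after seeing the data. The other alternatives were DESeq2 1.42.0 size factors, total counts alone, upper-quartile factors, no filter, a filter at 100 reads, prior counts of 0.5 and 10, the deeper library thinned to the shallower, totals without marker lists of other cell types, limits of 1.5-fold and 4-fold, and a bound of the interval that is itself at least 2-fold.

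The rule was tested on simulated data for the comparison of knockout with wild type, with counts drawn for the real genes and known changes in 200 of them. Without variation between replicates it recovered 100% of genes changed 4-fold and 100% of those changed 2.8-fold, 50 of 11394 unchanged genes passed, and 95.6% of intervals held the true ratio. These values hold for counting error alone. With an assumed coefficient of variation between replicates of 0.1, 0.2 and 0.3, 65.0%, 47.8% and 37.2% of intervals held the true ratio. Recovery of 4-fold changes was then 100%, 100% and 92%, and of 2.8-fold changes 99%, 91% and 82%. At 0.1, 82 of 11404 unchanged genes passed. With a coefficient of 0.2, 367 of 11382 unchanged genes passed, 132 of them over 10 CPM, and with 0.3 it was 1413 of 11347, 803 of them over 10 CPM. A planted length trend over 11381 genes (Spearman rho 0.71) was reduced to a rho of 0.00 by the subtraction, and genes changed 4-fold kept a median log2 ratio of 2.00.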

Results

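Gene expression was measured by RNA sequencing in cells sorted from mouse fetal liver at day 15.5 of development, from an Atf4 knockout and from a wild type. ATF4 is the transcription factor of the integrated stress response and drives genes of amino acid supply. The labels give the cell type as LSK, the lineage-negative, Sca-1-positive and c-Kit-positive fraction that is enriched for haematopoietic stem cells and multipotent progenitors. The sample titles carry the letters SC, which the labels do not explain, and the study's design covers both stromal and LSK cells, so the identity of the sorted fraction rests on the cell type label alone. The study asked which pathways depend on ATF4 in the stromal and LSK cells of the fetal liver. There was 1 library per group, so no difference below has a replicate check and no p-value is given. The knockout library held 15774824 reads in genes and the wild-type library 14049374, over 12898 genes, of which 11555 had at least 20 reads in both libraries together. Ratios are knockout over wild type after TMM scaling, each with a 95% interval that covers counting error only, and levels are in CPM (counts relative to the scaled library total).

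Atf4 itself had 1823 reads in the knockout library and 3507 in the wild-type library, or 107 and 270 CPM. It was 2.53-fold lower in the knockout library (95% interval 2.39 to 2.68), which leaves 39.5% of the wild-type level (37.3 to 41.8%). The direction matched the genotype labels. Reads were summed over the whole gene, so the table does not show from which part of the gene the remaining reads came.

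Genes of the ATF4 amino acid and stress programme were lower together in the knockout library. Of 32 tested members of the 3 ATF4 target lists, 30 had a log2 ratio below 0, 8 were at least 2-fold lower and 1 was at least 2-fold higher, with a median log2 ratio of -0.65 (95% order-statistic interval -0.77 to -0.46). Slc1a4, a transporter of neutral amino acids, had 8 reads against 220 and was 36.2-fold lower (18.1 to 84.9). Trib3, a pseudokinase induced by ATF4, had 5 reads against 77 and was 20.3-fold lower (8.32 to 64.2). Chac1, which degrades glutathione, had 0 reads against 27, at least 11.8-fold lower when the knockout library is set at a floor of 3 reads, while its counting interval reaches down to 8.99-fold. Among 12 genes of amino acid synthesis the median was -0.71 (-0.82 to -0.34), and Pycr1 of proline synthesis (7.02-fold, 3.75 to 14.3) and Phgdh of serine synthesis (2.07-fold, 1.99 to 2.15) were at least 2-fold lower. The other members among the 3 most abundant lay short of 2-fold, with Asns, asparagine synthetase, 1.55-fold lower (1.5 to 1.61) and Shmt2 of mitochondrial folate metabolism 1.65-fold lower (1.60 to 1.70). All 8 amino acid transporters had log2 ratios below 0, with a median of -0.59 and the glycine transporter Slc6a9 2.40-fold lower (2.10 to 2.75). Under scaling to total counts alone this median was -0.36 and that of the stress response targets -0.38. Phgdh and, narrowly, Herpud1 fell short of 2-fold under that scaling. Among 12 stress response targets the median was -0.59 (-1.28 to -0.24), also with Chac1 at its bound, and Ppp1r15a (2.43-fold) and Herpud1 (2.34-fold) joined Trib3 and Chac1 below the 2-fold line. Ddit4, an mTORC1 inhibitor with several other known inducers, was the exception at 2.67-fold higher (1.70 to 4.35). Marker lists of other cells were lower in the same comparison, with medians of -1.26 for hepatocyte, -0.70 for erythroid and -1.73 for granulocyte and monocyte genes. For each of the 3 ATF4 lists, 0 of 10000 random lists of the same size and expression had a median as low. The same held for nuclear oxidative phosphorylation genes (median -0.24), whose shift was largely removed by subtraction of length and GC trends. Random lists were matched on expression and not on transcript length. Such a rank, here or below, therefore does not by itself set a list apart.

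**Figure D1:**
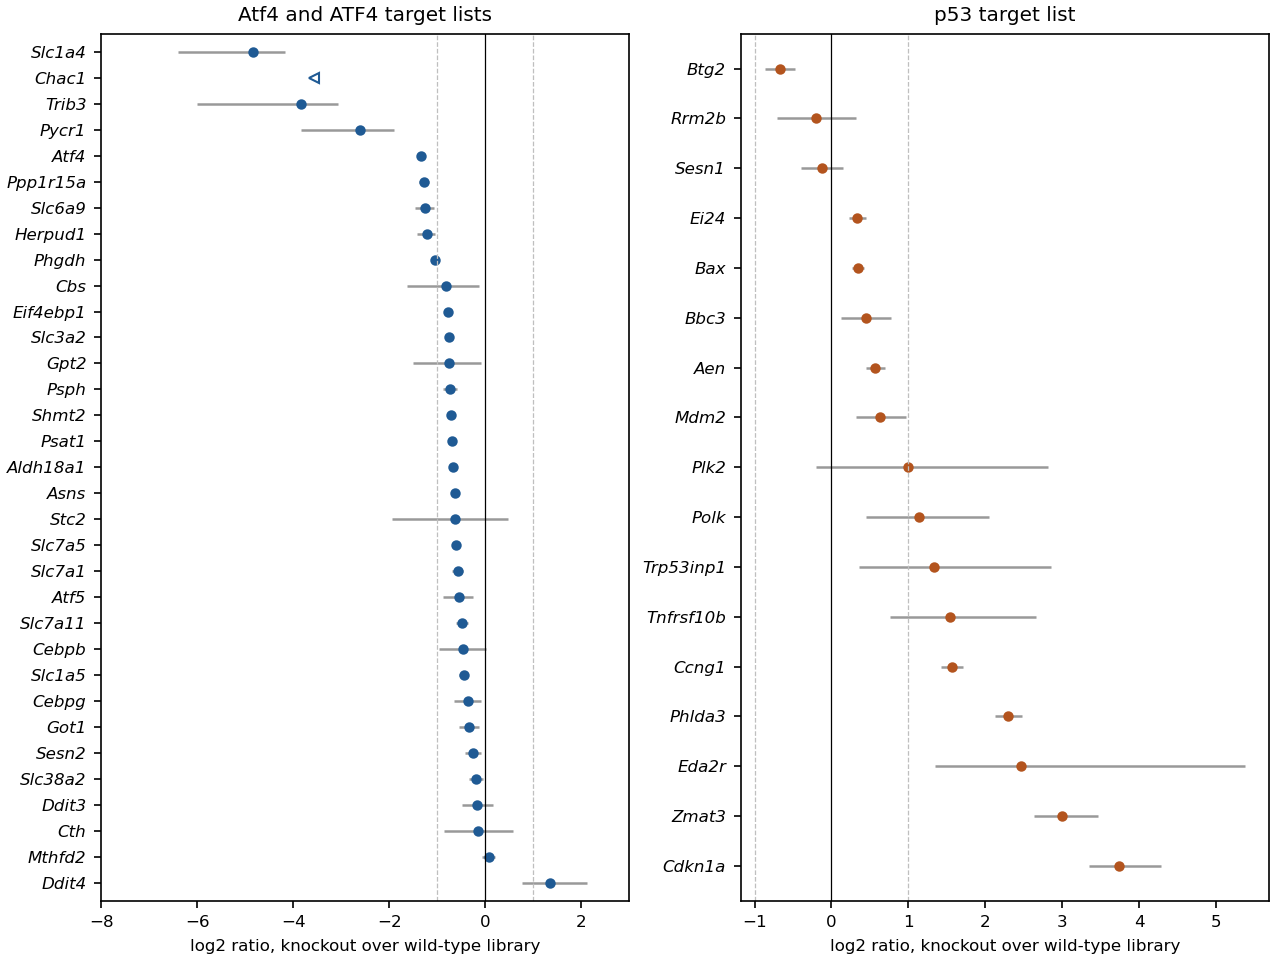
Log2 ratio of knockout over wild-type library for Atf4 with the 32 tested members of the ATF4 target lists (left) and for the 17 tested members of the p53 target list (right), 1 library per group. Points are the ratios, grey bars the 95% counting intervals, dashed lines the 2-fold limits, and the open triangle is the bound for Chac1, which had 0 reads in the knockout library. Of the ATF4 targets 30 lie below 0, and 8 p53 targets lie at or above the upper 2-fold limit with an interval that excludes 0.

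Aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, were lower only in part. Of 20 tested, Cars (3.32-fold, 2.96 to 3.74), Yars (2.24-fold, 2.11 to 2.39) and Iars (2.04-fold, 1.92 to 2.18) were at least 2-fold lower and 0 were higher. The list median was -0.14 (-0.73 to 0.04) and became 0.09 under scaling to total counts alone. Under that scaling Cars stayed at least 2-fold lower, while Yars and Iars fell short of the limit. Genes of the other arms of the unfolded protein response did not pass the 2-fold rule in either direction. The 15 endoplasmic reticulum chaperones and XBP1 or ATF6 targets had a median of -0.01 (-0.27 to 0.19), with Hspa5 at 182 CPM against 213 CPM, and 0.22 under scaling to total counts alone. Among 15 oxidative stress genes, Hmox1, haem oxygenase (2.5-fold, 1.85 to 3.40), and Mgst1 (2.76-fold, 1.59 to 4.97) were at least 2-fold lower, and the median was -0.19 (-0.31 to 0.11), or 0.04 under scaling to total counts alone and -0.093 when 100 reads were required. For 15 autophagy genes the median was -0.13 (-0.24 to 0.02), with 0 past the rule, and 0.10 under that scaling.

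Over all genes, 168 were at least 2-fold higher and 367 at least 2-fold lower in the knockout library with an interval that excluded 1, together 4.63% of those tested. The split depended on the scaling. With TMM factors 31.4% of these genes were higher, and with total counts alone 58.2% were (351 higher, 252 lower), because that scaling moved the median log2 ratio of all genes from 0.02 to 0.24. Most passing genes were rare, with a median level of 2.20 CPM, and among 7426 genes above 10 CPM 22 were higher and 72 lower. In simulated libraries the unchanged genes varied between replicates by an assumed coefficient of variation. At 0.1, 82 of 11404 unchanged genes passed the same rule, and at 0.2, 367 of 11382 did. Of the latter 132 were above 10 CPM, against 22 higher and 72 lower in the data. The setting of 0.2 therefore overstates the passing genes at those levels. With 1 library per group the true variation is unknown. How many genes would pass with no difference between genotypes therefore cannot be told.

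The genes with the largest ratios above 1 included several targets of p53, the transcription factor activated by DNA damage and other stress. Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, had 750 reads against 41 and was 13.9-fold higher in the knockout library (10.1 to 19.5). Zmat3, an RNA-binding protein, was 8.19-fold higher (6.19 to 11.03) and Phlda3, a repressor of AKT signalling, 4.91-fold higher (4.35 to 5.56). In the p53 target list 8 of 17 tested genes were at least 2-fold higher and 0 lower, and the median log2 ratio was 0.995 (0.35 to 1.57), which 0 of 10000 matched random lists reached. The median was 0.507 when 100 reads were required and 0.608 with a prior count of 10. Of the other 5 genes at least 2-fold higher, only Ccng1 (2.97-fold) had at least 100 reads in both libraries together. Eda2r (8.10-fold) had 32 reads against 3 and Tnfrsf10b (3.16-fold) 54 against 13. Trp53inp1 (2.85-fold) had 30 reads against 8 and Polk (2.32-fold) 58 against 19. Members short of 2-fold included Aen at 1.49-fold and Bax at 1.27-fold higher, and Btg2 was 1.59-fold lower (1.39 to 1.83). Among 13 apoptosis regulators, Apaf1, the scaffold of the apoptosome, was 2.12-fold higher (1.74 to 2.58) and the anti-apoptotic Bcl2l1 2.54-fold lower (2.30 to 2.81), with a list median of 0.10 (-0.40 to 0.31), or 0.32 under scaling to total counts alone and 0.019 after subtraction of length and GC trends.

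Other genes with large ratios above 1 were outside the lists. C2cd4a was 5.91-fold higher (5.01 to 7.002), the semaphorin receptor Plxnb2 4.91-fold (4.18 to 5.78), Bahcc1 4.36-fold (3.49 to 5.50), the chloride channel Ano1 4.12-fold (3.06 to 5.65) and Foxh1 3.18-fold (2.70 to 3.77). The Notch ligand Jag2 (63 reads against 5) was 9.57-fold higher, with a wide interval of 3.89 to 30.5. Psrc1 (2.98-fold), Vps13c (2.46-fold) and Rnf213 (2.27-fold) were among the most abundant genes in this direction. Of genes below 1 outside the lists, the receptor tyrosine kinase gene Mst1r had 3 reads against 151, a ratio of 66.3-fold lower (22.2 to 325). Fn3k, fructosamine-3-kinase, was 9.65-fold lower (6.44 to 15.0), Tmcc2 4.12-fold lower (3.98 to 4.28) and Prap1, with 2 reads against 40, 26.3-fold lower (6.83 to 225). Rpl29-ps5 (0 reads against 76) is a pseudogene copy of the abundant Rpl29, whose reads may be divided between copies or left uncounted, and its value is uncertain.

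Globin and several other red cell transcripts were lower in the knockout library. The 8 Hba and Hbb globin genes took 1.24% of reads (95% Wilson interval 1.23 to 1.24%) in the knockout library and 7.45% (7.43 to 7.46%) in the wild type. Hbb-b1 was 9.89-fold lower (9.78 to 10.005) and Hba-a1 5.94-fold lower (5.89 to 5.99), although reads of the near-identical adult copies Hbb-b1 with Hbb-b2, and Hba-a1 with Hba-a2, cannot be assigned surely to either. Alas2, the first enzyme of haem synthesis in red cells, was 6.66-fold lower (6.23 to 7.14), and Slc4a1, the band 3 anion exchanger, 3.64-fold lower (3.56 to 3.73). In the erythroid list 9 of 23 tested genes were at least 2-fold lower and 0 higher, with a median of -0.70 (-1.87 to -0.16) that 0 of 10000 random lists matched. The other 14 members did not pass the rule, among them Klf1 at 729 CPM against 939 CPM, Gata1 at 476 CPM against 534 CPM, the transferrin receptor Tfrc at a log2 ratio of 0.03, and the spectrin gene Spna1 1.41-fold higher (1.29 to 1.55).

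Markers of the labelled cell type could be read only in part. Of 15 progenitor genes 9 had a row in the table used here, and of 22 stem cell genes 11 had one. Ly6a, which encodes the Sca-1 antigen of the LSK gate, Cd34, Flt3 and Ptprc were among those with no row, so their levels were not analysed here. Kit had 106 CPM in the knockout library and 118 CPM in the wild type, and the 9 tested progenitor genes had a median log2 ratio of -0.16 (-0.36 to 0.27), with 0 past the 2-fold rule and 0.07 under scaling to total counts alone. Tal1 had 383 CPM against 429 CPM and Ikzf1 221 CPM against 183 CPM. Of the stem cell genes 7 had enough reads, and Gata2, a regulator of stem and progenitor cells, was 3.72-fold higher (2.60 to 5.45) at 10.6 CPM against 2.85 CPM. The median of these 7 genes was 0.28 (-0.83 to 1.85), and 12.8% of random lists reached it, with 0.51 under scaling to total counts alone and 0.16 after subtraction of length and GC trends. The erythroid list summed to 16110 CPM in the knockout library and 87624 CPM in the wild type, against 1174 CPM and 1263 CPM for the progenitor list. An LSK gate is meant to exclude maturing red cells, yet the erythroid sum was far above the progenitor sum in both libraries. Levels and ratios here, those of progenitor and stem cell genes included, therefore describe the sorted samples as a whole. The 7 tested stem cell genes summed to 92.9 CPM in the knockout library and 83.0 CPM in the wild type. Both sums were below Epor alone, at 352 CPM and 439 CPM. These levels do not by themselves bear out the LSK label. What share of the RNA came from LSK cells cannot be read, since Ly6a, Cd34, Flt3 and Ptprc had no row. Cytokine receptors did not pass the rule in any of 7 tested members (median -0.21, or 0.02 under scaling to total counts alone and -0.32 after subtraction of length and GC trends), with Epor at 352 CPM against 439 CPM. Of 12 integrins and homing molecules only Itgal, with 11 reads against 20, was at least 2-fold lower, and the median was -0.06, or 0.17 under that scaling, 0.04 with no filter or a filter at 100 reads and -0.13 after that subtraction.

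Hepatocyte transcripts, which an LSK gate is meant to exclude, were present in both libraries and lower in the knockout library, as were the rarer transcripts of mature myeloid cells. Among 20 hepatoblast and hepatocyte genes 13 were at least 2-fold lower and 0 higher, the median was -1.26 (-1.40 to -0.92), and their sum was 742 CPM against 1764 CPM, to be set beside 1174 CPM and 1263 CPM for the progenitor list. Albumin (Alb), at 168 CPM against 504 CPM, was 3.001-fold lower (2.87 to 3.14) and the fibrinogen gene Fga 4.50-fold lower (3.52 to 5.82). Of 11 granulocyte and monocyte genes 10 had a log2 ratio below 0 and 8 were at least 2-fold lower, with a median of -1.73 (-2.48 to -0.80), or -1.12 with a prior count of 10, S100a8 6.19-fold lower (3.64 to 11.2) and a list sum of 11.1 CPM against 34.7 CPM. Of 10 macrophage genes 9 had a log2 ratio below 0 and 6 were at least 2-fold lower (median -1.03, -1.82 to -0.68), among them the complement genes C1qa (4.43-fold), C1qb (3.04-fold) and C1qc (3.87-fold). For these 3 lists 0 of 10000 random lists had so low a median. Of 11 stromal genes Sparc (2.48-fold), Col4a1 (2.58-fold), Cxcl12 (2.04-fold) and Col1a1 (2.01-fold) were at least 2-fold lower, 2 members lay above 0, and the interval of the median (-0.71, -1.29 to 0.08) included 0. Among 9 megakaryocyte genes Pf4 was 2.32-fold lower (1.24 to 4.49), and the median of -0.45 (-0.85 to 0.28) became 0.00 when 100 reads were required, -0.25 under scaling to total counts and -0.28 with a prior count of 10. Of 4 endothelial genes Stab1 was 3.07-fold lower (1.51 to 6.63), and the list median was -0.19, or 0.04 under scaling to total counts alone, -0.77 with no filter on low counts, -0.11 when 100 reads were required and -0.085 after subtraction of length and GC trends. The single lymphoid gene tested, Lck, had 2.99 CPM against 3.62 CPM. No mast cell or basophil gene was tested.

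Angptl3, the secreted factor that the study's title links to ATF4, was scarce in these sorted cells, with 11 reads (0.644 CPM) in the knockout library and 36 reads (2.77 CPM) in the wild type. It was 4.31-fold lower in the knockout library (2.15 to 9.38). Angptl3 is made mainly by hepatocytes. Their gene list had a median log2 ratio of -1.26 in the same comparison, with members from -2.14 to -0.48. The value of -1.90 for Angptl3 lay within that range, so a drop beyond that of hepatocyte transcripts is not shown. Of 7 niche cytokines tested, Csf1 (3.38-fold), Vegfa (2.54-fold) and Cxcl12 were also at least 2-fold lower, with a median of -0.98 (-1.90 to 0.07) that 2 of 10000 random lists matched, or -0.50 when 100 reads were required. Angptl4 had 44.6 CPM against 42.5 CPM. In the list of fetal and imprinted genes, which shares Igf2 with the niche list and Dlk1 with the hepatocyte list, Meg3 was 3.25-fold lower (2.19 to 4.94) and Grb10 2.08-fold lower (1.95 to 2.21). The 17 members had a median of -0.41 (-0.83 to 0.38), or 0.06 when 100 reads were required and -0.19 under scaling to total counts.

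**Figure D2:**
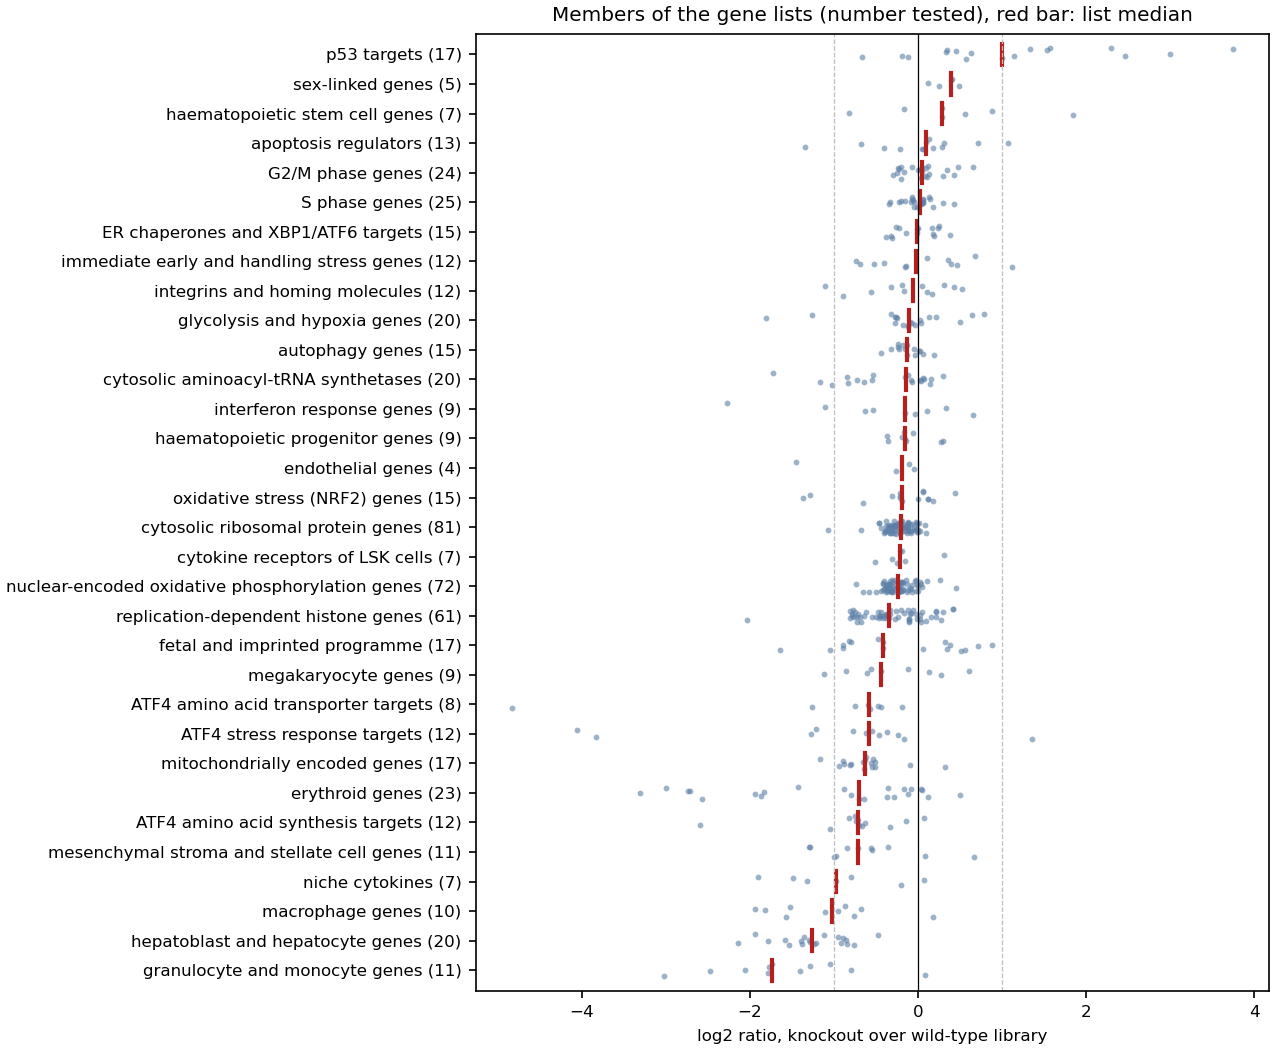
Log2 ratio of knockout over wild-type library for the members of each gene list with more than 1 tested member, 1 library per group. Points are genes, red bars list medians, dashed lines the 2-fold limits, and the number tested is in parentheses. Medians run from -1.73 for granulocyte and monocyte genes to 0.995 for p53 targets.

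Genes of the cell cycle did not separate the libraries. Of 25 S phase and 24 G2/M phase genes 0 passed the 2-fold rule, with medians of 0.02 (-0.08 to 0.06) and 0.04 (-0.17 to 0.12). The replication licensing gene Mcm2 had 850 CPM against 879 CPM, and Mki67 was 1.35-fold higher (1.29 to 1.41). Both medians moved with the processing, to 0.25 and 0.27 under scaling to total counts and to -0.04 and -0.01 after subtraction of length and GC trends. Among 20 genes of glycolysis and hypoxia the glucose transporter Slc2a1, which is also abundant in red cell precursors, was 3.50-fold lower (3.32 to 3.71) and Aldoc 2.797-fold lower (1.14 to 7.49), with a median of -0.11, or 0.12 under scaling to total counts alone and -0.019 after length and GC correction. Among 12 immediate early and handling stress genes Jun was 2.21-fold higher (1.55 to 3.20), and the median was -0.02 (-0.52 to 0.46), with a value of 0.21 under scaling to total counts, 0.13 after length and GC correction, -0.15 with no filter and 0.01 with a prior count of 10. Of 9 interferon response genes Rsad2 (5 reads against 25) and Xaf1 (11 reads against 20) were at least 2-fold lower, with a median of -0.15, or 0.06 under scaling to total counts alone, 0.11 when 100 reads were required and -0.28 after length and GC correction.

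The ratio between the libraries depended on transcript length. Across genes, which are not independent replicates, the log2 ratio increased with transcript length (Spearman rho 0.41 over 11344 genes) from a median of -0.20 in the shortest decile of genes to 0.34 in the longest, and it decreased with GC content (rho -0.26). These medians hold for TMM scaling, and total counts alone move all ratios up together, so that the difference between short and long genes stays while the sign for short genes depends on the scaling. Gene groups with short transcripts had medians below 0 under TMM scaling. Mitochondrially encoded genes took 3.90% of reads against 5.55%, and their 17 members had a median of -0.63 (-0.81 to -0.53), or -0.40 under scaling to total counts and -0.50 after subtraction of the length and GC trends. For 72 nuclear genes of oxidative phosphorylation the median was -0.24 (-0.31 to -0.20) with 0 past the rule, and -0.05 after subtraction or -0.017 under scaling to total counts. For 81 cytosolic ribosomal protein genes it was -0.20 (-0.26 to -0.16), which became -0.02 after subtraction and 0.02 under scaling to total counts alone. The 61 replication-dependent histone genes had a median of -0.35 (-0.41 to -0.12), or -0.11 after subtraction and -0.13 under scaling to total counts, and counts of such near-identical copies are uncertain. The ATF4 target medians after subtraction were -0.66, -0.75 and -0.61, and that of the p53 targets 0.99.

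**Figure D3:**
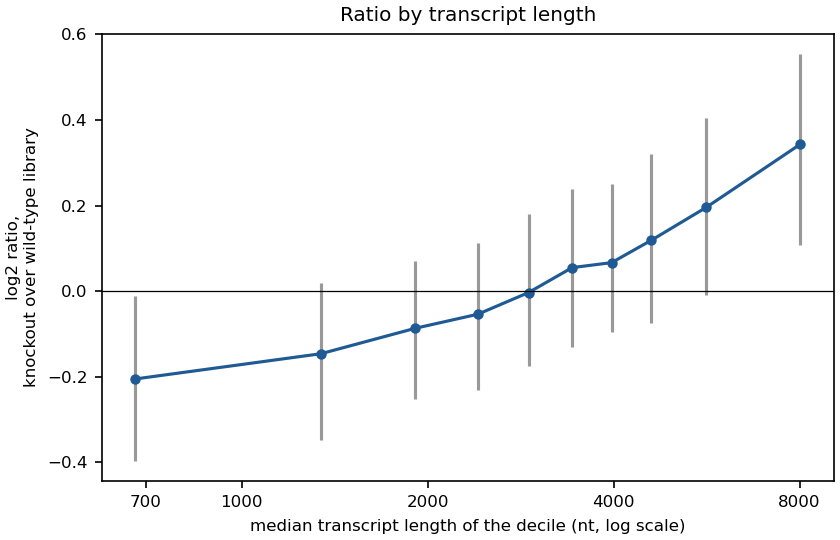
Median log2 ratio of knockout over wild-type library in 10 groups of genes of rising transcript length, against the median length of each group in nucleotides on a log scale. Points are medians over genes and grey bars the interquartile range. The median runs from -0.20 for the shortest decile to 0.34 for the longest.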

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

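The alternative of subtracted length and GC trends was chosen after the data were seen, and the others before. No paired analysis was possible because there was 1 library per group. Atf4 stayed lower, and the medians of the ATF4 target, p53, erythroid, granulocyte, macrophage and hepatocyte lists kept their sign, under every alternative run. When 100 reads were required, the granulocyte value rested on S100a9 alone (23 reads against 78) and the macrophage value on few genes. Under DESeq2 size factors, upper-quartile factors, both other prior counts, thinning, and totals without marker lists, counts of genes stayed within 1.5 times and list medians within their intervals. Counts moved with the limits by construction. Against 168 genes higher and 367 lower, requiring 100 reads gave 69 and 135, a 1.5-fold limit 650 and 678, a 4-fold limit 30 and 69, and a bound itself at least 2-fold 38 and 118. With total counts alone 351 were higher, because that scaling moves all ratios up together, from a median log2 ratio of 0.02 to 0.24. It moved list medians to 0.088 for aminoacyl-tRNA synthetases, 0.22 for endoplasmic reticulum chaperones, 0.10 for autophagy, 0.25 for S phase, 0.27 for G2/M phase, 0.32 for apoptosis, 0.040 for endothelial genes, 0.12 for glycolysis, -0.017 for oxidative phosphorylation, -0.40 for mitochondrially encoded and 0.62 for sex-linked genes. It reversed that of ribosomal protein genes to 0.025. Atf4 had a log2 ratio of -1.11 under it and -1.19 after length and GC correction. That correction moved medians to -0.054 for oxidative phosphorylation, -0.016 for ribosomal proteins, -0.50 for mitochondrially encoded, -0.11 for histone and 0.079 for sex-linked genes. Without a filter the lymphoid median was -1.70, since genes of few reads then joined the single one tested. Of the genes at least 2-fold apart, 117 higher and 304 lower genes remained after the correction, which left 142 and 338 in all. Depth limits rare genes most. At 36 reads against 11 the Angptl3 interval ran from 2.15 to 9.38-fold, and with no replicates none of these ranges measures variation between animals.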

Other observations

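The ratios of the aminoacyl-tRNA synthetases were spread widely around the list median of -0.14. In the knockout library 9 of the 20 cytosolic enzymes (Cars, Yars, Iars, Sars, Aars, Nars, Tars, Mars and Gars) had log2 ratios from -1.73 to -0.53, and the other 11 lay between -0.16 and 0.30. This division was drawn after the values were seen and was not tested. Outside the lists, 4 further genes lower in the knockout library were picked after their values were seen. Whether they share a cause with the lower red cell transcripts was not tested. Ypel4 was 6.44-fold lower (5.24 to 7.98), Ube2l6, a ubiquitin-conjugating enzyme, 2.92-fold lower (2.75 to 3.10), the nuclear exportin gene Xpo7 2.83-fold lower (2.52 to 3.19), and Slc25a37, the mitochondrial iron importer mitoferrin, 2.12-fold lower (2.02 to 2.23).

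Both libraries held transcripts of both sexes, with Xist at 205 reads and Ddx3y at 156 in the knockout library and 118 and 84 in the wild type. The 5 sex-linked genes had a median log2 ratio of 0.40, with 0 past the 2-fold rule.

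The tests below were chosen after the patterns were seen, the length and GC test of the p53 targets included, although its prediction was written before its own result.

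The first pattern is the lower level of mature erythroid transcripts in the knockout library. The length and GC trend shifts ratios by at most -0.30 on the log2 scale. The 9 of 23 erythroid genes past the 2-fold rule lay at -1.43 or below, too low for that shift to account for them. These 9 were picked by their low ratios, so the comparison does not cover the other 14 members. One uniform drop in RNA carried over from all other cell types would give globin and hepatocyte genes one ratio. The 9 tested globin genes, taken by gene family, had a median of -2.57 (-3.00 to -1.84), below the hepatocyte interval (-1.40 to -0.92). The interval of the whole erythroid list (-1.87 to -0.16) overlapped the hepatocyte one. The globin values therefore argue against one uniform drop for the globin genes only, a group chosen after the pattern was seen. Fewer mature erythroid cells in the knockout sort remain a candidate explanation (whole list median -0.70), and cannot be told apart from lower expression per cell with 1 library per group and no profile of the mature cells. An effect of the Atf4 genotype on red cell maturation stays open and untested, as does a difference in how well the sort removed such cells.

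The second pattern is the higher level of p53 targets in the knockout library. After subtraction of length and GC trends the list median was 0.99 (0.47 to 1.52). By the corrected ratios 8 of 17 genes were at least 2-fold higher. Both values argue against the trend as the whole cause. A smaller share of red cell RNA would raise the genes of the remaining cells alike. The progenitor genes had a median of -0.16 (-0.36 to 0.27), but they cannot decide this. Which cells of the sample their reads came from is not known, and Ly6a, Cd34, Flt3 and Ptprc had no row. Handling stress would be expected to raise immediate early genes as much as p53 targets. The immediate early median was -0.020 (-0.52 to 0.46), although Jun was 2.21-fold higher. That interval lay below the p53 median of 0.995 but overlapped its interval (0.35 to 1.57), so the comparison does not decide on handling stress. A response tied to the Atf4 genotype remains a hypothesis that needs replicated libraries, and a difference between the animals or preparations used stays open.

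The third pattern is that 39.5% of the wild-type level of Atf4 reads remained in the knockout library. Wild-type cells or RNA mixed into the sample at that share would hold every gene at or above it, yet 16 genes had an upper bound below 0.197, which is 0.5 of the Atf4 ratio. Among them were Slc1a4, Trib3 and Chac1, with 13 reads pooled against 324, or 3.05% of the wild-type level (1.61 to 5.29%). These 3 were picked by that bound, and the pooled interval does not allow for the choice. Below the lower bound of the Atf4 ratio itself lay 51 genes, fewer than the 289 that make up 2.5% of those tested, so that count alone does not decide. The 16 genes argue against admixture as the whole source of the Atf4 reads. Transcript retained from the targeted allele and reads shared with pseudogene copies were not tested.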
